A study of Mus musculus with 12 samples.

How the data were processed

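The samples are 12 RNA sequencing libraries of mouse CD4+ T cells in 6 groups of 2: Treg and Tconv from the tumour of TB mice, the spleen of TB mice and the spleen of normal mice. Per the labels' protocols, C57BL/6 mice received TC-1 cells intravenously, tissues were taken after 3 weeks, CD4+ cells were enriched by negative selection and sorted by GFP, RNA was extracted with a micro column kit, and libraries were made with a stranded mRNA kit and sequenced on a NextSeq500. Per the labels, the processing names STAR, featureCounts and the mm10 assembly, with no versions. The deposited values are raw read counts per gene, 1 column per library, as whole numbers with no scaling by the authors. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain. Titles were used as replicate numbers, and for normal mice they differ from the number in the sample description (Treg 1 and 2 carry 2 and 3, Tconv 1 and 2 carry 1 and 3). The table holds 24062 genes, of which 5873 had 0 counts in every library, and holds no mitochondrially encoded gene.

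Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (13509 genes), scaled by TMM (factors 0.942 to 1.07) and fitted with 1 quasi-likelihood model of all 12 libraries and 6 group means, which leaves 6 residual degrees of freedom. The common biological coefficient of variation was 0.0863. There were 7 comparisons of 2 groups and 2 interactions, each a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Between replicates the variance was 3.56 to 17.0 times that of counting alone (chi-square per gene). Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group, and it covers counting error only. The procedure was tested on simulated counts of 13027 genes: in the tumour comparison of Treg it recovered 77% of 100 genes changed by 1 log2 unit and 60% of 100 changed by 0.5, with 8 false among 145 calls, and in the site interaction 61% and 22%, with 1 false among 84. In the simulation all groups had the same mean and spread per gene. Only these genes changed, in tumour Treg alone and as many up as down. In the data far more genes were called and the spread differed between groups, so these rates may not hold there.

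Before the data were examined, 26 gene lists (455 members, of which 5 were not matched and 6 were matched by synonym), the comparisons and most alternatives were fixed: Treg identity, tissue and effector Treg, IL-33 and ST2 signalling, checkpoints and costimulation, naive and lymphoid homing, chemokine receptors of tissue homing, helper cytokines and their transcription factors, cytotoxic effector, proliferation, interferon response, glycolysis and hypoxia, oxidative phosphorylation, lipid uptake and synthesis, immediate early and dissociation stress, cytosolic ribosomal proteins, and markers of B cells, CD8 T cells, NK cells, macrophages and monocytes, dendritic cells, neutrophils, mast cells and basophils, lung and tumour epithelium, endothelium, fibroblasts and erythroid cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Activated T cells also express members of the macrophage, dendritic, B cell and NK lists. Genes were named by a rule fixed at the same time: Foxp3 and Il1rl1 in every comparison, with Il33 and Il1rap in 6 of them; the 6 called genes with the largest increase and the 6 with the largest decrease among genes of mean log2 CPM of at least 3 whose libraries did not overlap between groups, passing over gene models, receptor segments and pseudogenes; and up to 3 called members of each list. Which of the list members were printed was chosen after their values were seen, and some genes that the rule names are not reported here.

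Of the genes named in the text, 144 were looked up in GENCODE annotation of the same assembly: 143 matched, 36 share exonic bases with a gene on the opposite strand and 7 with one on the same strand. Genes named only in the closing sections, such as Socs1, Egr2, Mvk and Fkbp5, were not looked up. Values of Dusp5, Il12rb2, Tnfrsf18, Sox4, Ube2c, Fdps and Foxp3, which overlap other genes over more than a small part of their exons, and of families with near-identical copies, such as ribosomal proteins, Hspa1a and Hspa1b, Gbp, Gzm and Klr genes, are uncertain to that extent. Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, library-size scaling, other expression filters, a robust fit, fits of only the groups compared, replicate blocks, thinning to the smallest total, stricter thresholds and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.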

Results

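Messenger RNA was sequenced from 12 libraries of mouse CD4+ T cells that had been sorted by GFP into regulatory T cells (Treg, GFP-positive) and conventional T cells (Tconv, GFP-negative). The cells came from 3 sites: the tumour and the spleen of tumour-bearing (TB) mice, 3 weeks after intravenous injection of 500000 TC-1 cells, and the spleen of normal mice. The sample descriptions mark the tumour libraries LG, which may stand for lung, and the spleen libraries SP. No group came from the tumour's organ in mice without tumour. A change between tumour and spleen therefore cannot be told apart from a difference between that organ and spleen. TC-1 is a transplantable mouse tumour line derived from lung epithelium. The 3 sites and 2 cell types make 6 groups of 2 libraries each, so n = 2 for every level given here. Total counts per library ran from 18624132 to 24111546, and 13509 of the 24062 genes in the table had enough counts to be tested. Levels are counts-per-million values (CPM) ± SD between the 2 libraries, and changes are log2 fold changes ± SE with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test. The largest changes are given among well-counted genes, meaning called genes with a mean log2 CPM of at least 3 over the 12 libraries and, in a comparison of 2 groups, no overlap between their libraries. Gene models, receptor segments and pseudogenes are passed over, so genes outside these limits may have changed more. The labels do not say that the 2 replicates of a group came from separate mice, so the p values measure the spread between these samples. The first principal component held 65.0% of the variance and separated the tumour libraries (−141 to −80.0) from the spleen libraries (29.7 to 86.4). The second held 23.3% and separated Treg (−65.2 to −29.0) from Tconv (34.7 to 64.8).

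Foxp3, the transcription factor that defines Treg cells, checked the sort. It lay between 989 and 1246 CPM in the 6 Treg libraries and between 11.5 and 19.6 CPM in the 6 Tconv libraries. The series is about interleukin 33 (IL-33) and its receptor ST2, which Il1rl1 encodes. Il1rl1 (chromosome 1, 40429570 to 40465415, mm10) was highest in tumour Treg at 451 ± 14.5 CPM, followed by tumour Tconv at 79.3 ± 27.2, TB spleen Treg at 73.4 ± 19.1 and normal spleen Treg at 48.5 ± 15.5. It was lowest in spleen Tconv, at 2.55 ± 1.63 CPM in TB mice (71 and 31 counts) and 1.05 ± 0.404 in normal mice (15 and 28 counts). Il33 itself (chromosome 19, 29925114 to 29960718) was counted only at low levels, and only in tumour libraries above 1 count. Its level was 2.61 ± 0.259 CPM in tumour Treg (56 and 64 counts) and 1.67 ± 1.56 CPM in tumour Tconv (10 and 61 counts). The 4 spleen groups held 0 or 1 count per library, which allows up to 0.0739 CPM in a group of 0 counts, for counting error only. Il1rap, the shared coreceptor of the interleukin 1 family (chromosome 16, 26581704 to 26730117), was similar in level everywhere, from 25.3 ± 0.249 CPM in TB spleen Tconv to 32.1 ± 1.12 CPM in tumour Tconv.

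**Figure D1:**
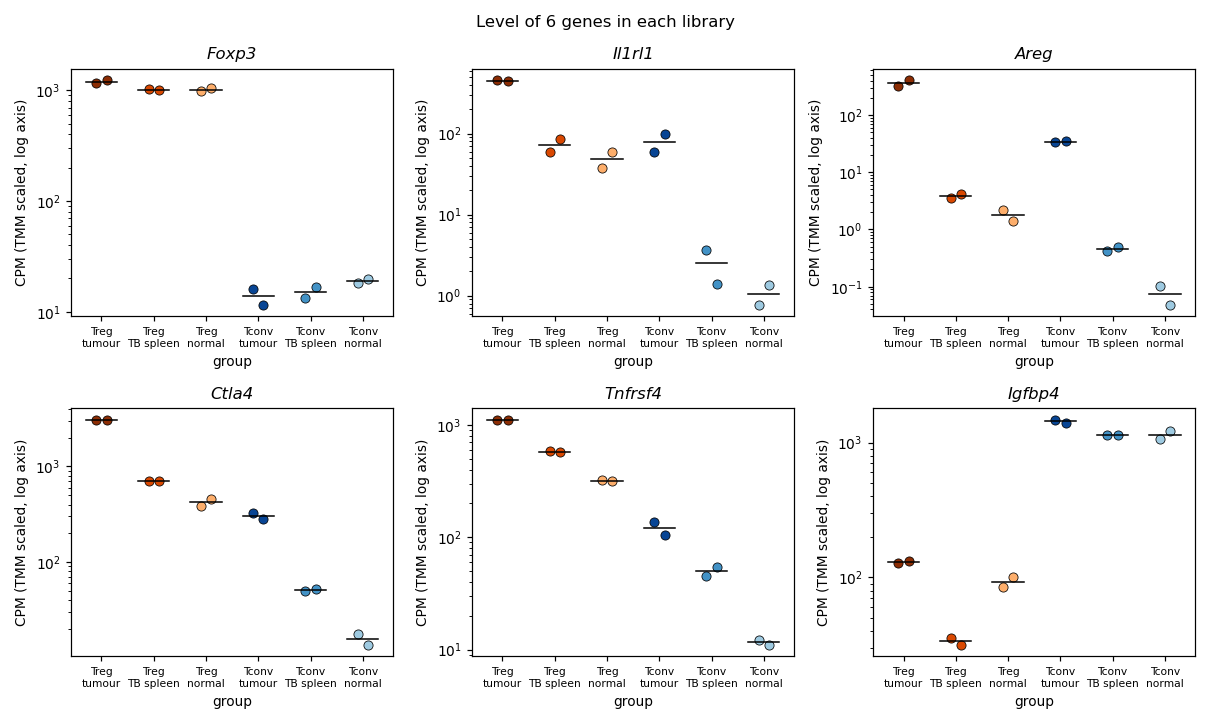
Levels of key genes in each library, in CPM on a logarithmic axis, by group (TB, tumour-bearing); points are libraries and bars are group means. Foxp3 separates the Treg from the Tconv libraries, and Il1rl1 reaches 451 CPM in tumour Treg against 1.05 CPM in normal spleen Tconv.

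The first comparison asked how Treg in the tumour differed from Treg in the spleen of TB mice. Il1rl1 was higher by 2.62 ± 0.27 (adjusted p = 5.07e-06), Areg, an epidermal growth factor family ligand, by 6.56 ± 0.15 (367 ± 63.7 against 3.89 ± 0.419 CPM), and Ctla4, an inhibitory receptor, by 2.13 ± 0.11 (3064 ± 30.3 against 701 ± 2.87 CPM). Foxp3 was not called (0.24 ± 0.11, adjusted p = 0.0800) and passed the test only without tumour Tconv library 1 (adjusted p = 0.0214) or 2 (0.0271). Il1rap did not differ (−0.03 ± 0.08, adjusted p = 0.755), and Il33 was at least 41.9-fold higher against a floor of 3 counts over the spleen group. In all, 8299 genes passed, 4427 higher and 3872 lower, of which 2319 and 889 changed at least 2-fold. Among well-counted genes the largest increases were in Plac8 (6.07 ± 0.28), Emp1 (5.28 ± 0.41), Gem (4.83 ± 0.11), the AP-1 subunit Fosb (4.74 ± 0.70), App (4.58 ± 0.28) and the chemokine Cxcl10 (4.54 ± 0.19). Fosb rested on uneven spleen libraries, with 6.68 without TB spleen Treg library 1 and 3.94 without library 2. The largest decreases among them were in Gucy1a3 (−4.83 ± 0.19), Slc16a5 (−3.92 ± 0.21), the costimulatory ligand Tnfsf14 (−3.55 ± 0.27), Tmie (−3.15 ± 0.20), Tbc1d4 (−2.81 ± 0.13) and Pou2af1 (−2.73 ± 0.27).

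By gene list, 23 of 25 tissue and effector Treg genes were higher in tumour Treg and 0 were lower (camera adjusted p = 1.35e-20, 0.122 estimated), among them the costimulator Icos (1.99 ± 0.06) and the transcriptional regulator Id2 (3.04 ± 0.13). For each list the first adjusted p assumes a preset correlation between genes, and the value marked estimated uses the correlation estimated from these libraries. The Treg identity list was mixed, with 12 of 20 higher and 4 lower (adjusted p = 0.0425, 0.541 estimated). It contains the integrin gene Itgae (2.48 ± 0.14) and the receptor gene Gpr83, which fell by 2.68 ± 0.11. Of 15 genes of IL-33 and ST2 signalling, 5 rose and 3 fell (adjusted p = 0.471), with the NF-κB inhibitor Nfkbia at 1.46 ± 0.07 and the kinase Irak2 at 0.68 ± 0.08. Chemokine receptors of tissue homing rose in 11 of 15 and fell in 1 (adjusted p = 1.45e-05, 0.232 estimated), including Cxcr6 (4.32 ± 0.19) and Ccr8 (2.38 ± 0.12). Checkpoints and costimulation rose in 12 of 20 and fell in 6 (adjusted p = 0.00611, 0.443 estimated), with Havcr2, which encodes TIM-3, at 3.91 ± 0.21. Cytotoxic effector genes rose in 12 of 15 (adjusted p = 1.45e-05, 0.183 estimated), including Gzmb (3.55 ± 0.26) and Ccl5 (3.20 ± 0.20). Naive and lymphoid homing genes fell in 11 of 20 and rose in 6 (adjusted p = 0.0214, 0.541 estimated). Nsg2 fell by 2.33 ± 0.12, while Ccr7, the lymph node homing receptor, rose by 1.72 ± 0.08. Helper cytokines and their transcription factors went both ways, with 9 of 18 higher and 4 lower (adjusted p = 0.728), and the anti-inflammatory cytokine Il10 rose by 3.10 ± 0.24.

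Proliferation genes rose in 24 of 26 and fell in 1 in tumour Treg (adjusted p = 0.00198, 0.541 estimated), for example the topoisomerase Top2a (1.37 ± 0.15). Interferon response genes rose in 28 of 30 (adjusted p = 1.38e-15, 0.183 estimated), with Isg15 at 2.46 ± 0.13. Glycolysis and hypoxia genes rose in 17 of 24 and fell in 2 (adjusted p = 3.13e-05, 0.122 estimated), with Ndrg1 at 3.30 ± 0.07 and the HIF prolyl hydroxylase Egln3 at 1.96 ± 0.12. Genes of lipid uptake and synthesis rose in 17 of 24 and fell in 3 (adjusted p = 1.53e-05, 0.135 estimated), including the triglyceride synthesis enzymes Dgat1 (3.02 ± 0.09) and Dgat2 (3.04 ± 0.12). Immediate early and dissociation stress genes rose in 21 of 26 and fell in 2 (adjusted p = 4.54e-13, 0.122 estimated), including the nuclear receptors Nr4a1 (3.33 ± 0.13), Nr4a2 (4.09 ± 0.15) and Nr4a3 (3.57 ± 0.13). Oxidative phosphorylation rose in 15 of 26 and fell in 1 without passing the list test (adjusted p = 0.0995; 0.00957 without tumour Treg library 2), with Cox5a at 0.81 ± 0.12. Cytosolic ribosomal proteins fell in 12 of 32 and rose in 0, with Rps15 at −0.50 ± 0.07. The list missed the threshold (adjusted p = 0.0532) and passed it when any of 10 libraries was left out (0.00525 without tumour Treg library 1, 0.0144 without TB spleen Treg library 2, up to 0.0488 without TB spleen Tconv library 2). Adjusted over the list alone, the counts of all these lists were the same except for 11 ribosomal proteins lower. With library-size scaling the median of all genes moved by −0.161 and the calls split into 3490 higher and 5268 lower (39.8% higher against 53.3%). The list median changed sign for IL-33 and ST2 signalling (0.03 to −0.13), with 4 higher and 5 lower, and for no other list. The Treg identity list lost its call (adjusted p = 0.0533, and 0.0618 with a replicate block), and the ribosomal list gained one (0.0402).

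Transcripts of other cell types were also higher in the tumour libraries of both cell types. In tumour Treg 9 of 9 fibroblast markers rose (adjusted p = 1.24e-09, 0.166 estimated), with the collagen gene Col3a1 at 181 ± 7.27 CPM and at least 2909-fold above spleen. Markers rose in 12 of 16 for lung and tumour epithelium (adjusted p = 3.03e-05, 0.183 estimated), with the surfactant gene Sftpb at least 158-fold higher. Macrophage and monocyte markers rose in 16 of 16 (adjusted p = 4.56e-05, 0.281 estimated). The lysozyme gene Lyz2 was higher by 7.32 ± 0.51, or 6.67 without TB spleen Treg library 1 and 8.47 without library 2. Dendritic cell markers rose in 8 of 10 (adjusted p = 3.88e-05, 0.135 estimated). The marker lists that did not pass were those of neutrophils (5 of 12 higher, 1 lower, adjusted p = 0.145, but 0.0360 without TB spleen Treg library 2), mast cells and basophils (3 of 4 higher, 1 lower, adjusted p = 0.260), and endothelium (4 of 7 higher, 1 lower, adjusted p = 0.336). Others were those of B cells (2 of 5 higher, 1 lower or 2 over the list alone, median −0.06 and mean 0.46, adjusted p = 0.661), CD8 T cells (2 of 2 higher, adjusted p = 0.406) and NK cells (0 of 6 higher, 3 lower, adjusted p = 0.0903). The 1 tested erythroid marker was not called. As shares of the total count, fibroblast markers made up 0.0715% and 0.0793% in tumour Treg and 0.0393% and 0.105% in tumour Tconv, against at most 6.39e-04% in spleen. Il33 moved with them between the tumour Tconv libraries, at 10 and 61 counts beside 1689 and 5205 of Col3a1, and tumour Treg held 56 and 64 counts beside 4036 to 4300 of Col3a1. The counts do not show which cells the Il33 transcripts came from. Macrophage markers made up 0.0731% to 0.134% in the 4 tumour libraries against 0.0300% to 0.0513% in spleen, and immediate early and stress genes 1.20% to 1.53% against 0.236% to 0.424%. Against TB spleen of the same cell type, these shares were higher in the same libraries as the shares of the tissue Treg and interferon lists.

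**Figure D2:**
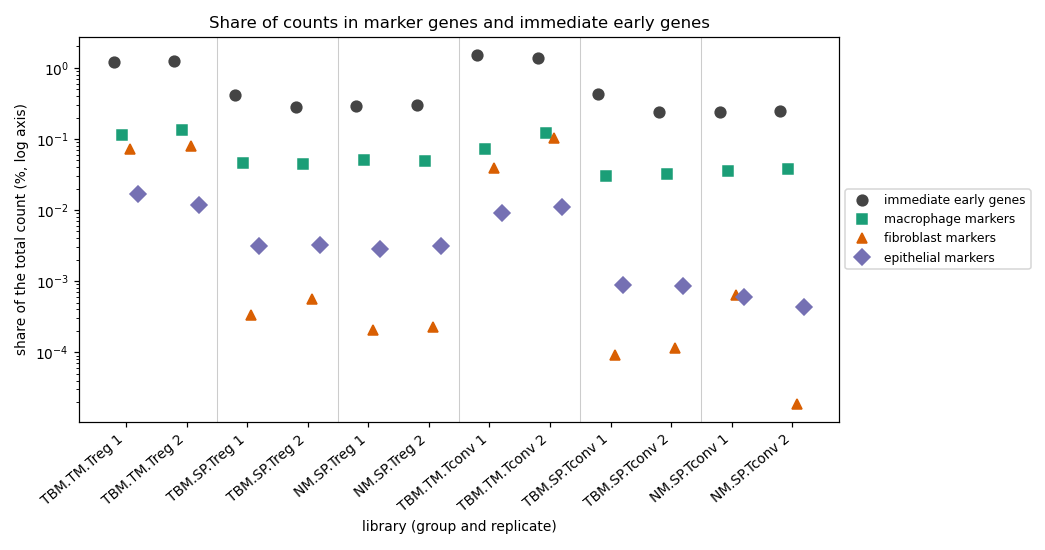
Share of each library's total count, in percent on a logarithmic axis, held by marker lists of other cell types and by immediate early and stress genes (points are libraries; TBM, tumour-bearing mice; NM, normal mice; TM, tumour; SP, spleen). Fibroblast markers reach 0.105% in a tumour Tconv library and stay at or below 6.39e-04% in spleen.

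In Tconv the same comparison of tumour with TB spleen gave 6639 genes, 3562 higher and 3077 lower, of which 2206 and 425 changed at least 2-fold. Il1rl1 rose by 5.01 ± 0.39 (adjusted p = 8.37e-07), from 2.55 to 79.3 CPM, and by 5.83 without TB spleen Tconv library 1. Il1rap rose slightly, by 0.34 ± 0.08 (adjusted p = 0.00453). Foxp3 did not differ (−0.14 ± 0.15, adjusted p = 0.456), but passed at −0.38 without tumour Tconv library 1 (adjusted p = 0.0288). Among well-counted genes the largest increases besides Il1rl1 were in the AP-1 subunit Fosl2 (5.75 ± 0.18), Nr4a2 (5.33 ± 0.18), Nr4a3 (4.88 ± 0.15), Emp1 (4.86 ± 0.39; 4.12 without tumour Tconv library 2) and the MAP kinase phosphatase Dusp5 (4.32 ± 0.11). The largest decreases among them were in Lpar5 (−2.92 ± 0.16), Ddit4 (−2.88 ± 0.26), Slc16a5 (−2.70 ± 0.09), Ptpn5 (−2.65 ± 0.39), Tnfsf14 (−2.45 ± 0.21) and the metalloproteinase Mmp9 (−2.31 ± 0.42; −3.42 without tumour Tconv library 2). Il17a, the Th17 cytokine, was at 5.39 ± 0.916 CPM in tumour Tconv and at least 74.4-fold higher than in TB spleen Tconv, while the helper cytokine Il21 fell by 3.03 ± 0.42.

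Of the tissue and effector Treg list, 20 of 25 genes were higher and 1 was lower in tumour Tconv (adjusted p = 5.54e-18, 0.0801 estimated), including Areg (6.21 ± 0.23), Icos (2.16 ± 0.07) and the transcription factor Irf4 (2.50 ± 0.10). Immediate early and stress genes rose in 22 of 26 and fell in 1 (adjusted p = 1.88e-24, 0.0801 estimated). Proliferation rose in 21 of 26 and fell in 1 (adjusted p = 1.06e-06, 0.449 estimated), with Top2a at 1.91 ± 0.17 and the ubiquitin carrier Ube2c at 3.37 ± 0.32. Interferon response rose in 24 of 30 (adjusted p = 2.63e-08, 0.448 estimated), with Cxcl10 at 3.75 ± 0.21 and Gbp2 at 1.21 ± 0.08. Glycolysis and hypoxia rose in 12 of 24 and fell in 3 (adjusted p = 0.00639, 0.289 estimated; 0.0763 without tumour Tconv library 1), with Ndrg1 at 1.63 ± 0.07, Hif1a at 1.32 ± 0.09 and hexokinase 2 (Hk2) at 3.26 ± 0.23. Lipid uptake and synthesis rose in 11 of 24 and fell in 1 (adjusted p = 0.00521, 0.392 estimated), with Dgat1 at 2.90 ± 0.10. Chemokine receptors rose in 9 of 15 and fell in 2 (adjusted p = 0.00672, 0.481 estimated), with Ccr8 at 3.41 ± 0.16. The call was lost without tumour Tconv library 1 (adjusted p = 0.103) or TB spleen Tconv library 1 (0.0582). Macrophage markers (16 of 16, adjusted p = 2.31e-06, 0.392 estimated) and fibroblast markers (9 of 9, adjusted p = 2.13e-12, 0.246 estimated) rose in these libraries too. Lyz2 was at 9.28 ± 0.62, or 8.43 without tumour Tconv library 2.

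Markers of lung epithelium passed as well (12 of 16 higher, adjusted p = 2.23e-05, 0.392 estimated). So did those of dendritic cells (6 of 10 higher, 1 lower, adjusted p = 0.0369, 0.430 estimated), a call lost without tumour Tconv library 1 or 2 (0.124 and 0.0648) or TB spleen Tconv library 1 (0.0820). The remaining lists in Tconv did not pass, and most had members called in both directions. Treg identity had 7 of 20 higher and 6 lower (adjusted p = 0.264), among them Ctla4 (2.59 ± 0.12) and the costimulator Tnfrsf4 (1.27 ± 0.11). IL-33 and ST2 signalling had 5 of 15 higher and 4 lower (adjusted p = 0.694), with Nfkbia at 1.10 ± 0.07 and Irak4 at −0.68 ± 0.08. Its median was 0.07, and −0.04 with library-size scaling. Checkpoints had 10 of 20 higher and 7 lower (adjusted p = 0.182), with the inhibitory receptor Cd160 at −3.66 ± 0.19. Cytotoxic effector genes had 6 of 15 higher and 3 lower (adjusted p = 0.809), with Gzmk at 1.64 ± 0.18 and Id2 at −0.90 ± 0.12. Of naive and lymphoid homing genes, 5 of 20 were higher and 3 lower (adjusted p = 0.429), with the trafficking genes Ccr7 (1.24 ± 0.08), Klf2 (1.20 ± 0.10) and S1pr1 (1.18 ± 0.12) among the higher. The median of that list was 0.08, and −0.03 with library-size scaling. Oxidative phosphorylation had 2 of 26 higher and 4 lower (adjusted p = 0.484), with a median of −0.02, or 0.02 with DESeq2 size factors. Ribosomal proteins had 5 of 32 higher and 0 lower (1 higher over the list alone; adjusted p = 0.484), B cell markers 0 of 5 higher and 2 lower (adjusted p = 0.484) and CD8 markers 0 of 2 called (1 higher and 1 lower over the list alone; adjusted p = 0.898). Helper cytokines had 8 of 18 higher and 4 lower (adjusted p = 0.484) and NK markers 1 of 6 higher and 2 lower (adjusted p = 0.484). Neutrophil markers had 8 of 12 higher and 1 lower (adjusted p = 0.203), mast cell and basophil markers 3 of 4 and 1 (adjusted p = 0.295) and endothelial markers 4 of 7 and 1 (adjusted p = 0.251). Adjusted over the list alone, 0 oxidative phosphorylation genes were higher and 2 lower, IL-33 signalling and checkpoints had 6 and 11 higher, and cytotoxic and lipid genes 4 and 2 lower. Library-size scaling moved the median of all genes by −0.108 and split the calls into 3092 higher and 4365 lower (41.5% higher against 53.7%).

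The 2 cell types shared much of this change. In all, 2729 genes were higher in the tumour in both (1167 if the lists were independent), and 1963 were lower in both (882). The log2 changes correlated across genes at r = 0.885, where genes are not independent replicates. Markers of fibroblasts, macrophages and lung epithelium, and immediate early and stress genes, also rose in both. The overlap and the correlation may therefore include RNA of other cells or effects of tissue handling. How much of them this makes up was not tested. The test of the difference itself, Treg change minus Tconv change, passed for 3337 genes, 1574 positive and 1763 negative, and for 2161 without TB spleen Treg library 1. On the log2 scale Il1rl1 rose less in Treg than in Tconv, by −2.39 ± 0.50 (adjusted p = 0.00460; −3.21 without TB spleen Tconv library 1), starting from a higher spleen level. In CPM its rise was larger in Treg (73.4 to 451) than in Tconv (2.55 to 79.3). The difference rests on low counts in TB spleen Tconv (71 and 31). RNA of stromal cells was not excluded as a source of Il1rl1 in tumour Tconv. Il1rap differed by −0.38 ± 0.12 (adjusted p = 0.0342), a call lost when any of 9 of the 12 libraries was left out (adjusted p up to 0.123, without TB spleen Treg library 2). Foxp3 did not pass (0.38 ± 0.18, adjusted p = 0.157; 0.62 and 0.0102 without tumour Tconv library 1), nor did Il33 (adjusted p = 0.522). Among well-counted genes the largest positive differences were in Plac8 (5.96 ± 0.39), Cxcr6 (5.23 ± 0.23), Id2 (3.94 ± 0.17), App (3.42 ± 0.35), Serpina3f (3.41 ± 0.32) and the monocyte chemokine receptor Ccr2 (3.30 ± 0.37). The largest negative ones among them were in Gucy1a3 (−3.57 ± 0.25), the proton pump subunit Atp6v0d2 (−3.07 ± 0.54; −3.66 and −2.02 without tumour Tconv library 1 or 2), Sh3bgrl2 (−3.02 ± 0.28), the semaphorin receptor Plxnb2 (−2.94 ± 0.49; −2.28 without tumour Tconv library 2), the RANK ligand Tnfsf11 (−2.88 ± 0.13) and Trim13 (−2.70 ± 0.22). Tumour Tconv library 2 held more macrophage markers than library 1 (0.120% against 0.0731% of the count) and more fibroblast markers (0.105% against 0.0393%). Whether RNA of other cells contributes to Atp6v0d2 and Plxnb2 was not tested.

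**Figure D3:**
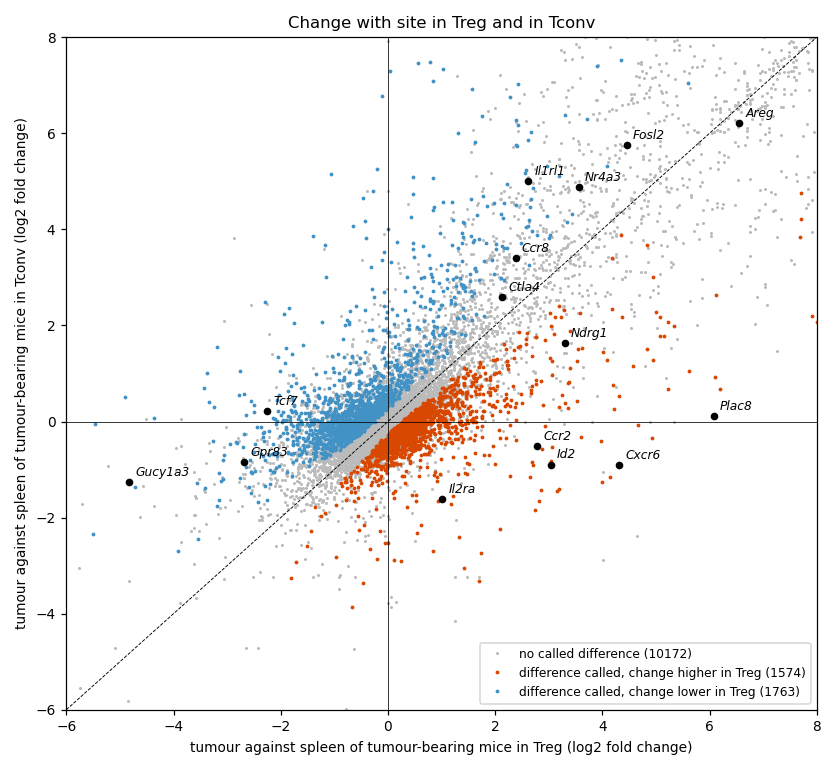
Log2 fold change of tumour over tumour-bearing (TB) spleen in Treg against that in Tconv for the 13509 tested genes, with genes whose 2 changes differ by the test in colour. 1574 genes have a positive and 1763 a negative difference, and 406 genes lie outside the axes.

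Cytotoxic effector genes changed more upward in Treg than in Tconv, with a positive difference in 9 of 15 and a negative one in 1 (adjusted p = 3.51e-10, 0.433 estimated), including Ccl5 (2.88 ± 0.27) and Nkg7 (2.26 ± 0.27). Interferon response differed positively in 15 of 30 and negatively in 1 (adjusted p = 7.95e-06, 0.688 estimated), with Usp18 at 0.91 ± 0.15 and Oasl1 at 1.34 ± 0.23. Oxidative phosphorylation differed positively in 8 of 26 (adjusted p = 0.00134, 0.688 estimated). Naive and lymphoid homing differed negatively in 12 of 20 and positively in 4 (adjusted p = 7.95e-06, 0.688 estimated), with the T cell factor Tcf7 at −2.46 ± 0.19, Nsg2 at −1.99 ± 0.17 and Igfbp4 at 1.61 ± 0.13. Ribosomal proteins differed negatively in 12 of 32 (adjusted p = 8.53e-04, 0.688 estimated). Immediate early and stress genes differed negatively in 6 of 26 and positively in 1 (adjusted p = 0.0329, 0.688 estimated). That call was lost without tumour Treg library 2 (0.0614), TB spleen Treg library 1 (0.222), tumour Tconv library 1 (0.0697) or TB spleen Tconv library 2 (0.330). Dendritic cell markers differed positively in 4 of 10 (adjusted p = 0.00438, 0.688 estimated). Treg identity members went both ways, 6 of 20 positive and 7 negative (median −0.09, mean 0.05, adjusted p = 0.704; 0.00136 without TB spleen Tconv library 1). Other lists that did not pass gained a call in some alternatives. Chemokine receptors (5 of 15 positive, 5 negative, adjusted p = 0.0636) passed with a replicate block (0.00657) and without tumour Treg library 1 (0.0468), TB spleen Treg library 2 (0.0232), normal spleen Treg library 1 (0.0368) or 2 (0.0360) or TB spleen Tconv library 1 (2.03e-04). Proliferation (2 of 26 positive, 7 negative, 0.0636) passed with the block (0.0178) and without tumour Treg library 1 (0.0468), TB spleen Treg library 1 (0.00293) or tumour Tconv library 1 (2.40e-04). Glycolysis and hypoxia (7 of 24 positive, 3 negative, 0.0636) passed without tumour Treg library 1 (0.0300), TB spleen Treg library 1 (0.0422) or TB spleen Tconv library 1 (0.0115). Tissue and effector Treg genes (8 of 25 positive, 5 negative, 0.173) and checkpoints (4 of 20 positive, 1 negative, 0.173) passed without tumour Tconv library 1 (0.0402 and 0.0362) or TB spleen Tconv library 1 (0.00230 and 0.0170). Il2ra, the IL-2 receptor α chain, was at 2.63 ± 0.21, Socs2 at 2.35 ± 0.26 and Gpr83 at −1.83 ± 0.17. Irf4 (−1.71 ± 0.13) and Batf (−1.06 ± 0.12), a pair of cooperating transcription factors, rose less in Treg on the log2 scale. Tbx21, which encodes T-bet (2.41 ± 0.28), Ndrg1 (1.68 ± 0.09), Myd88 (0.51 ± 0.09) and Irak2 (0.48 ± 0.12) had positive differences. Adjusted over the list alone, 10 cytotoxic, 17 interferon and 9 oxidative phosphorylation genes differed positively and 15 ribosomal and 8 Treg identity genes negatively.

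The next comparisons set Treg against Tconv at each site, asking which genes mark Treg there. In the tumour, 7277 genes differed, 3676 higher and 3601 lower in Treg (1413 and 1008 at least 2-fold). Besides Foxp3 (6.45 ± 0.15), the largest increases among well-counted genes were in Klrg1, a receptor of effector Treg (7.73 ± 0.33; 8.66 without tumour Tconv library 2), Lrrc32, which encodes the latent TGF-β receptor GARP (6.73 ± 0.22), Il2ra (6.42 ± 0.18), Cd83 (5.70 ± 0.15) and Itgae (5.67 ± 0.17). Il1rl1 was higher by 2.50 ± 0.27 (adjusted p = 5.68e-06). Il33 did not differ (0.62 ± 0.61, adjusted p = 0.445) and its direction rests on single libraries. It was at −0.11 (adjusted p = 0.835) without tumour Tconv library 1 and at 2.19 (adjusted p = 0.00696) without library 2. Il1rap was lower by −0.23 ± 0.08 (adjusted p = 0.0288), a call lost without tumour Treg library 1 (0.172) or tumour Tconv library 2 (0.119). The largest decreases among well-counted genes were in the neuropeptide receptor gene Vipr1 (−6.36 ± 0.17), Dapl1 (−5.95 ± 0.16), Tdrp (−5.34 ± 0.16), Hs3st3b1 (−5.34 ± 0.14), Slc16a5 (−4.91 ± 0.19) and Atp8b4 (−4.58 ± 0.13). All 20 Treg identity genes were higher (adjusted p = 3.04e-53, 0.0140 estimated), with the Helios gene Ikzf2 at 4.95 ± 0.12. Tissue and effector Treg genes were higher in 24 of 25 (adjusted p = 6.41e-29, 0.0224 estimated), with Tnfrsf9 at 5.13 ± 0.12, Areg at 3.42 ± 0.12 and Penk at 3.33 ± 0.12.

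Checkpoints were higher in tumour Treg in 15 of 20 and lower in 3 (adjusted p = 1.75e-16, 0.0512 estimated), with Ctla4 at 3.33 ± 0.12 and Tnfrsf4 at 3.21 ± 0.12. Of naive and lymphoid homing genes, 17 of 20 were lower and 1 was higher (adjusted p = 1.25e-27, 0.0340 estimated), with Tcf7 at −4.21 ± 0.15 and Igfbp4 at −3.47 ± 0.10. Chemokine receptors were higher in 11 of 15 and lower in 1 (adjusted p = 8.28e-09, 0.173 estimated), with Ccr3 at 7.30 ± 0.34 and Ccr8 at 3.16 ± 0.12. Ribosomal proteins were lower in 29 of 32 (adjusted p = 3.75e-13, 0.113 estimated), with Rpl8 at −1.43 ± 0.09. Interferon response was higher in 24 of 30 and lower in 1 (adjusted p = 3.45e-05, 0.522 estimated), with Gbp3 at 2.46 ± 0.10. Glycolysis and hypoxia was higher in 15 of 24 and lower in 3 (adjusted p = 0.00225, 0.161 estimated), with the lactate transporter Slc16a3 at 3.58 ± 0.16. Proliferation was higher in 18 of 26 and lower in 3 (adjusted p = 0.0241, 0.742 estimated), a call lost without tumour Treg library 1 (0.0526), and 19 were higher over the list alone. Cytotoxic genes were split, 7 of 15 higher and 6 lower (median 0.58, mean −0.17, adjusted p = 0.829), with Gzmk at −5.19 ± 0.23 and perforin (Prf1) at −2.00 ± 0.10. Cd40lg, the CD40 ligand of helper cells, was lower by −3.78 ± 0.11. Irak2 (1.47 ± 0.08), Nfkbia (1.00 ± 0.07) and Dgat2 (5.42 ± 0.15) were higher. Fibroblast markers differed in 0 of 9 (adjusted p = 0.883), but the list passed without tumour Tconv library 2 (0.0167). Dendritic cell markers were higher in 5 of 10 and lower in 2 (adjusted p = 0.0133, 0.322 estimated), a call lost without tumour Tconv library 1 (0.226) or 2 (0.0893). NK markers were lower in 5 of 6 and higher in 1 without passing (adjusted p = 0.0613). They passed with a replicate block (0.0148) or without tumour Tconv library 1 (0.0227) or 2 (0.0352).

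In the spleen 5447 genes differed between Treg and Tconv of TB mice (2833 higher, 2614 lower; 1433 and 562 at least 2-fold) and 5478 in normal mice (2950 higher, 2528 lower; 1500 and 480 at least 2-fold). Foxp3 was higher in Treg by 6.07 ± 0.15 in TB and 5.75 ± 0.14 in normal spleen, and Il1rl1 by 4.89 ± 0.39 (5.71 without TB spleen Tconv library 1) and 5.51 ± 0.46. Il1rap did not differ (0.14 ± 0.08, adjusted p = 0.204, and 0.08 ± 0.08, adjusted p = 0.467), and Il33 was at or under the counting floor. In TB spleen the largest increases among well-counted genes, besides Foxp3, were in Lrrc32 (9.14 ± 0.29; 8.46 and 10.79 without TB spleen Tconv library 1 or 2), Klrg1 (7.20 ± 0.41), Itgae (6.91 ± 0.23; 7.75 without TB spleen Tconv library 2), the laminin gene Lamc1 (5.65 ± 0.26) and Sdc4 (5.06 ± 0.36). The largest decreases among them were in Atp8b4 (−5.91 ± 0.15), the phosphodiesterase Pde3b (−5.60 ± 0.13), Igfbp4 (−5.08 ± 0.11), Vipr1 (−5.08 ± 0.15), Cxcr6 (−4.98 ± 0.18) and Dapl1 (−4.79 ± 0.14). In normal spleen the largest increases among well-counted genes were in Lrrc32 (11.65 ± 0.36), Sdc4 (6.99 ± 0.47), Itgae (6.40 ± 0.23), Klrg1 (6.34 ± 0.38), Il2ra (5.96 ± 0.17) and the decoy receptor Il1r2 (5.91 ± 0.47; 5.32 without normal spleen Treg library 1). The largest decreases among them were in Atp8b4 (−6.28 ± 0.15), Pde3b (−5.14 ± 0.13), App (−4.77 ± 0.26), Vipr1 (−4.48 ± 0.14), Cxcr6 (−4.37 ± 0.18) and Dapl1 (−4.30 ± 0.12). The limit on counts holds for the mean over all 12 libraries, so the lower group of a large fold may hold few counts. The SE can then understate the uncertainty. Lrrc32 in TB spleen moved by more than its SE of 0.29 with either Tconv library left out.

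All 20 Treg identity genes were higher in Treg in both spleens (adjusted p = 3.53e-79 in TB and 5.29e-104 in normal spleen; adjusted p = 0.00114 and 0.00175 with an estimated correlation), including Ikzf2 (3.95 ± 0.11 and 4.66 ± 0.11), Ctla4 (3.78 ± 0.12 and 4.75 ± 0.14) and Tnfrsf4 (3.54 ± 0.12 and 4.78 ± 0.13). Tissue and effector Treg genes were higher in 23 and 24 of 25 and lower in 1 and 1 (adjusted p = 9.18e-33 and 1.20e-37; adjusted p = 0.0160 and 0.0131 with an estimated correlation), with Penk at 3.49 ± 0.12 and 5.52 ± 0.15, Tnfrsf9 at 4.31 ± 0.12 and 3.95 ± 0.12, and Ccr8 at 4.19 ± 0.15 and 4.90 ± 0.20. Naive and lymphoid homing was lower in 17 and 17 of 20 (adjusted p = 6.09e-25 and 5.19e-19; adjusted p = 0.0453 and 0.0801 with an estimated correlation). Cytotoxic effector genes were lower in 10 and 10 of 15 and higher in 2 and 2 (adjusted p = 2.19e-07 and 2.26e-06; adjusted p = 0.172 and 0.251 with an estimated correlation), with Prf1 at −2.35 ± 0.10 and −2.61 ± 0.10. NK markers were lower in 4 and 3 of 6 and higher in 1 and 1 without passing (medians −2.28 and −2.40, adjusted p = 0.221 and 0.445). They made up 0.00686% and 0.0101% of the count in TB spleen Tconv against 0.00211% and 0.00181% in TB spleen Treg, and 0.00470% and 0.00403% against 0.00227% and 0.00173% in normal spleen. Proliferation was higher in 20 and 18 of 26 and lower in 2 and 2 (adjusted p = 1.14e-05 and 0.00336; adjusted p = 0.448 and 0.739 with an estimated correlation), with Mki67 at 2.55 ± 0.24 and 2.24 ± 0.25. Ribosomal proteins were lower in 25 and 25 of 32 (adjusted p = 2.70e-09 and 1.31e-07; adjusted p = 0.172 and 0.251 with an estimated correlation), or 27 and 26 adjusted over the list alone. Checkpoints (15 and 15 of 20 higher, 3 and 2 lower; adjusted p = 9.97e-20 and 1.53e-25; adjusted p = 0.0379 and 0.0268 with an estimated correlation) were higher. So were chemokine receptors (11 and 9 of 15 higher, or 12 and 10 over the list alone, and 2 and 3 lower; adjusted p = 7.41e-07 and 3.15e-04; adjusted p = 0.205 and 0.416 with an estimated correlation), with Ccr6 at 4.40 ± 0.15 and 3.71 ± 0.16. The B cell receptor gene Cd79b was higher in TB spleen Treg by 3.80 ± 0.16. B cell markers, Cd79b among them, made up 0.00451% and 0.00460% of the count in TB spleen Treg. In TB spleen Tconv they made up 0.00173% and 0.00244%. RNA of B cells was not tested as a source of Cd79b. Irak2 (0.99 ± 0.08 and 1.36 ± 0.09) and Nfkbia (0.64 ± 0.07 and 0.84 ± 0.07) were higher in Treg of both spleens. In TB spleen some lists passed only with 1 library left out. These were interferon response without Treg library 1 (adjusted p = 0.0131) or Tconv library 2 (0.0365), glycolysis without Tconv library 2 (0.0369), Treg library 2 (0.0463) or tumour Treg library 1 (0.0469) or 2 (0.0468), and immediate early genes (median −0.13, mean 0.17) without Tconv library 1 (0.0181). Across sites, 2018 genes were higher and 1881 lower in Treg in both tumour and TB spleen (771 and 697 if independent), and 764 were higher and 276 lower by at least 2-fold at all 3 sites.

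**Figure D4:**
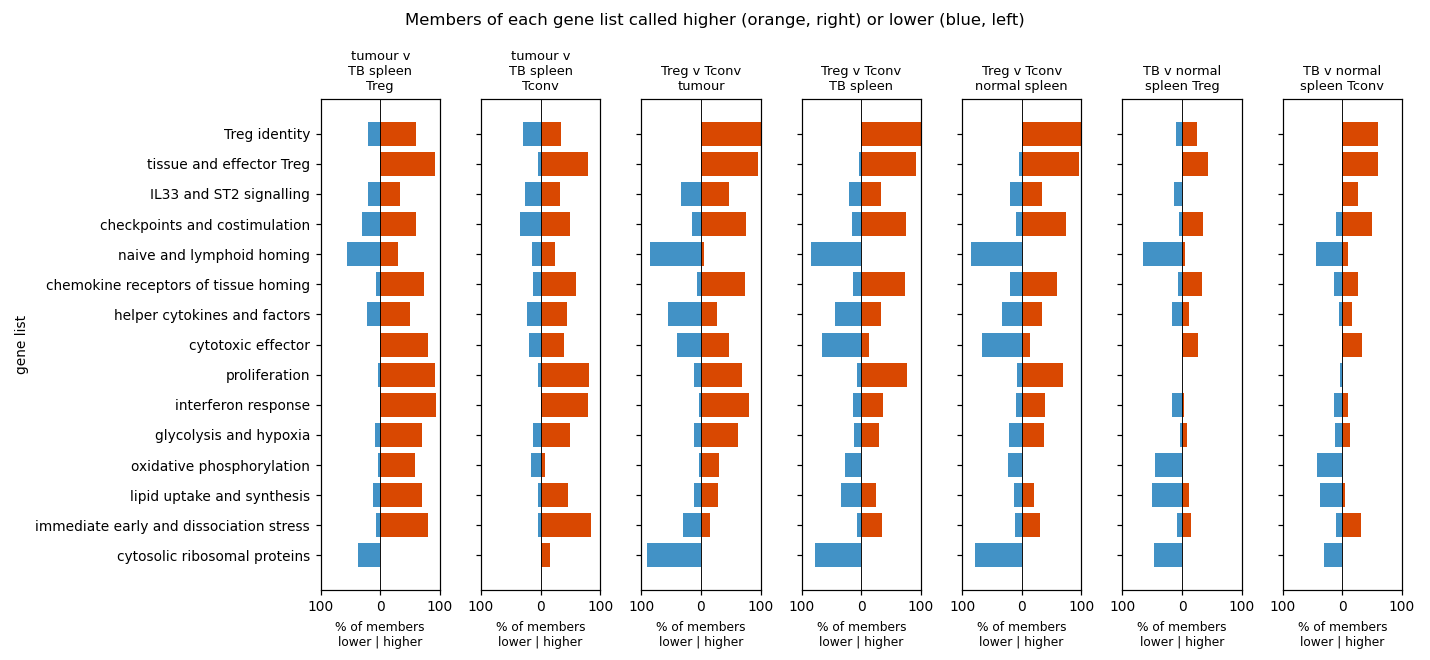
Percent of the tested members of each functional gene list called higher (right) or lower (left) in the 7 comparisons of 2 groups (TB, tumour-bearing). All 20 Treg identity genes are higher in Treg at each of the 3 sites.

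The last comparisons asked whether spleen T cells of TB mice differed from those of normal mice. In Treg 2066 genes differed, 918 higher and 1148 lower, of which 261 and 40 changed at least 2-fold. The count was 818 with a block on the number in the sample description and 3670 with only the groups compared. The Treg identity list rose in 5 of 20 and fell in 2 without passing (7 and 5 over the list alone; adjusted p = 0.0705, but 0.0376 with library-size scaling). Tnfrsf18 (0.86 ± 0.10), Tnfrsf4 (0.86 ± 0.11) and Ctla4 (0.73 ± 0.11) were among the higher, while Foxp3 (0.00 ± 0.11, adjusted p = 1) and Il1rl1 (0.60 ± 0.27, adjusted p = 0.153) were not called. Among well-counted genes the largest increases were in Zscan10 (3.84 ± 0.25), Fosl2 (2.67 ± 0.18), Rnf157 (2.46 ± 0.17), Ston1 (2.36 ± 0.15), Ctla2a (2.33 ± 0.23) and the hypoxia factor Epas1 (2.25 ± 0.16). Among their largest decreases were those in Igfbp4 (−1.47 ± 0.10), Sox4 (−1.44 ± 0.33; not called without TB spleen Treg library 2, adjusted p = 0.116, or normal spleen Treg library 1, 0.0849), Id3 (−1.43 ± 0.23), Ms4a4c (−1.29 ± 0.12) and the squalene epoxidase Sqle (−1.27 ± 0.16). Tissue and effector Treg genes rose in 11 of 25 (14 adjusted over the list alone; adjusted p = 1.54e-09, 0.298 estimated), with Ccr8 at 1.27 ± 0.12, Gzmb at 2.19 ± 0.27 and Id2 at 1.08 ± 0.13. Naive and lymphoid homing fell in 13 of 20 and rose in 1 (15 lower over the list alone; adjusted p = 3.44e-12, 0.298 estimated), with Il7r at 1.23 ± 0.12. Of the signalling genes below ST2, Myd88 (−0.30 ± 0.06) and Mapk14 (−0.22 ± 0.06) fell. Myd88 lost its call without TB spleen Treg library 1 (0.0643) or 2 (0.0567) or normal spleen Treg library 2 (0.0881), and Mapk14 without any 1 of the 4 libraries compared (0.1002, 0.146, 0.142 and 0.115). Chemokine receptors rose in 5 of 15 and fell in 1 (9 higher over the list alone; adjusted p = 7.88e-05, 0.505 estimated), with the fractalkine receptor Cx3cr1 at 3.28 ± 0.25. Checkpoints rose in 7 of 20 and fell in 1 (adjusted p = 0.00129, 0.593 estimated).

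In TB spleen Treg oxidative phosphorylation fell in 12 of 26 (adjusted p = 9.26e-08, 0.298 estimated), with the ATP synthase gene Atp5o at −0.44 ± 0.07, and ribosomal proteins fell in 15 of 32 (adjusted p = 1.68e-08, 0.298 estimated), with Rps15 at −0.45 ± 0.07. Lipid uptake and synthesis fell in 12 of 24 and rose in 3 (adjusted p = 0.00118, 0.298 estimated), with the sterol regulator Srebf2 at −0.71 ± 0.06, Fdps at −1.12 ± 0.11 and Dgat1 at 1.10 ± 0.09. Adjusted over the list alone, 14, 21 and 13 were lower. With library-size scaling these directions held, with 7, 13 and 8 lower, and the calls split into 1281 higher and 645 lower (66.5% higher against 44.4%). Hif1a (0.91 ± 0.09) and Slc16a3 (1.33 ± 0.15) rose, although the glycolysis and hypoxia list did not pass (adjusted p = 0.385). Cytotoxic genes rose in 4 of 15 (adjusted p = 0.0117, 0.684 estimated), and the proliferation list passed with 0 members called (adjusted p = 0.0206, 0.755 estimated). Both lost the call without TB spleen Treg library 2 (0.0711 and 0.418), and proliferation also without normal spleen Treg library 1 (0.0964). Macrophage markers rose as a list with 1 of 16 higher and 1 lower (adjusted p = 0.0117, 0.755 estimated; 0.174 without TB spleen Treg library 2). Interferon response (0.00203) and immediate early genes (0.00173) passed only without TB spleen Treg library 2, neutrophil markers (3.21e-04) only without TB spleen Treg library 1. The immediate early and stress share was 0.413% and 0.278% in the TB spleen Treg libraries and 0.292% and 0.299% in normal spleen Treg. The number of called genes fell to 856 or 683 without TB spleen Treg library 1 or 2 and to 1010 or 512 without normal spleen Treg library 1 or 2.

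In spleen Tconv 2328 genes differed between TB and normal mice, 1316 higher and 1012 lower (419 and 18 at least 2-fold). The count was 1189 with a block on the number in the sample description. Treg identity rose in 12 of 20 and fell in 0 (14 over the list alone; adjusted p = 9.79e-24, 0.0983 estimated), with Tnfrsf4 at 2.10 ± 0.13 (49.7 ± 6.18 against 11.6 ± 0.893 CPM), Ctla4 at 1.70 ± 0.13 and the CD73 gene Nt5e at 1.09 ± 0.09. Foxp3 was not called (−0.32 ± 0.14, adjusted p = 0.141), but passed without tumour Tconv library 1 (adjusted p = 0.0438) or 2 (0.0413), and Il1rl1 was not called (1.22 ± 0.73, adjusted p = 0.283; 0.39 without TB spleen Tconv library 1). Among well-counted genes the largest increases were in Neb, which encodes the muscle protein nebulin (5.89 ± 0.24), Ston1 (4.03 ± 0.19), Ier5l (3.98 ± 0.66), Coro2a (3.52 ± 0.15), Gzmb (3.34 ± 0.49; 2.73 without TB spleen Tconv library 2) and Il1r2 (3.10 ± 0.64; not called without TB spleen Tconv library 2, 0.0540, or normal spleen Tconv library 2, 0.0712). Among their largest decreases were those in the sterol synthesis gene Cyp51 (−1.13 ± 0.13), Prdm16 (−1.03 ± 0.22), Rap1gap2 (−0.98 ± 0.23) and Id3 (−0.95 ± 0.25). Prdm16, Rap1gap2 and Id3 lost the call without TB spleen Tconv library 1 (adjusted p = 0.0750, 0.0997 and 0.114) or normal spleen Tconv library 1 (0.0594, 0.0980 and 0.0888), and Id3 without TB spleen Tconv library 2 (0.0928) or normal spleen Tconv library 2 (0.0962). Tissue and effector Treg genes rose in 15 of 25 (17 over the list alone; adjusted p = 8.14e-18, 0.0983 estimated), with Penk at 2.30 ± 0.17, Tigit at 2.22 ± 0.24, Bhlhe40 at 1.68 ± 0.22 and Ccr8 at 1.99 ± 0.27. Checkpoints rose in 10 of 20 and fell in 2 (adjusted p = 8.84e-12, 0.179 estimated), with Tnfrsf18 at 1.27 ± 0.10.

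Naive and lymphoid homing fell in 9 of 20 and rose in 2 in TB spleen Tconv (adjusted p = 1.96e-04, 0.433 estimated), with Foxo1 at −0.53 ± 0.07, Dapl1 at −0.71 ± 0.10 and Ccr7 at −0.49 ± 0.08. Cytotoxic genes rose in 5 of 15 (adjusted p = 0.00163, 0.433 estimated; 0.0830 without TB spleen Tconv library 2), with Klrc1 at 2.12 ± 0.32 and Fasl at 0.85 ± 0.16. NK markers rose in 3 of 6 and fell in 0 without passing (adjusted p = 0.0931), with 0.00686% and 0.0101% of the count in TB spleen Tconv libraries 1 and 2 against 0.00470% and 0.00403% in normal spleen Tconv. Il12rb2, a chain of the IL-12 receptor, rose by 1.88 ± 0.25. In the IL-33 and ST2 signalling list 4 of 15 rose (adjusted p = 0.293), with Irak2 at 0.50 ± 0.09, Nfkbia at 0.34 ± 0.07 and Sigirr at 0.56 ± 0.13. Nfkbia and Sigirr lost the call without TB spleen Tconv library 1 (0.0556 and 0.0808) or normal spleen Tconv library 1 (0.0828 and 0.109), and Sigirr without TB spleen Tconv library 2 (0.0503). Oxidative phosphorylation fell in 11 of 26 (adjusted p = 2.50e-06, 0.320 estimated), with Atp5o at −0.35 ± 0.07 (not called without TB spleen Tconv library 1, 0.0667, or normal spleen Tconv library 2, 0.0621). Lipid uptake and synthesis fell in 9 of 24 and rose in 1 (adjusted p = 0.00137, 0.320 estimated), with Srebf2 at −0.54 ± 0.06, Hmgcs1 at −0.69 ± 0.11 and Cpt1a at 0.88 ± 0.12. Ribosomal proteins fell in 10 of 32 (adjusted p = 1.57e-05, 0.365 estimated). Adjusted over the list alone, 13, 10 and 14 were lower. Library-size scaling kept these directions with 4, 9 and 6 lower, and split the calls into 1757 higher and 482 lower (78.5% higher against 56.5%). Interferon response went both ways, 3 of 30 higher and 4 lower (median −0.05, mean 0.04, adjusted p = 0.392; 0.0131 without TB spleen Tconv library 2; median 0.02 with library-size scaling), with Gbp2 at −0.58 ± 0.08 and Mx1 at 1.47 ± 0.27. Hif1a rose by 0.77 ± 0.09. Immediate early and stress genes, at 0.424% and 0.236% of the count in the TB spleen Tconv libraries, rose in 8 of 26 and fell in 3 without passing (adjusted p = 0.0756; 2.66e-06 without TB spleen Tconv library 2, 0.0258 and 0.0257 without TB spleen Treg library 1 or 2, 0.0268 without normal spleen Tconv library 2, and 0.0373 with a replicate block). Without TB spleen Tconv library 1, chemokine receptors (0.00333), NK markers and dendritic markers (each 0.0150) passed, NK markers also without tumour Tconv library 1 (0.0439) or 2 (0.0407), and fibroblast markers without normal spleen Tconv library 2 (0.00982). The count of called genes fell to 1045 or 1450 without TB spleen Tconv library 1 or 2, and to 985 or 751 without normal spleen Tconv library 1 or 2.

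Of the genes called in spleen, 526 were higher and 597 lower in TB mice in both cell types (89.4 and 86.0 if independent). Over all tested genes the log2 changes correlated at r = 0.332, against 0.885 for the change between TB spleen and tumour. The test of the difference, Treg change minus Tconv change, passed for 115 genes, 30 positive and 85 negative. Foxp3 (0.32 ± 0.18, adjusted p = 0.726), Il1rl1 (−0.62 ± 0.78, adjusted p = 0.941; 0.21 without TB spleen Tconv library 1) and Irak2 (−0.37 ± 0.12, adjusted p = 0.336) were not among them. Among well-counted genes, positive differences were largest in Epas1 (2.50 ± 0.21), Fam46a (2.01 ± 0.20), Fosl2 (1.97 ± 0.25), Rgs2 (1.55 ± 0.15), Rnf157 (1.51 ± 0.24; not called without TB spleen Treg library 2, 0.0567, or normal spleen Tconv library 2, 0.0812) and the cAMP-responsive modulator Crem (1.24 ± 0.13). Cx3cr1, below that limit of counts, was at 3.86 ± 0.33. Negative differences among well-counted genes were largest in Neb (−4.46 ± 0.31), Coro2a (−3.44 ± 0.19), Socs2 (−2.76 ± 0.30), Il2ra (−2.17 ± 0.21), Penk (−2.04 ± 0.20) and Gucy1a3 (−1.99 ± 0.21). Treg identity genes rose less in Treg than in Tconv, with 9 of 20 negative and 0 positive (13 negative over the list alone; adjusted p = 1.73e-32, 0.0443 estimated), including Nt5e (−0.99 ± 0.12) and Tnfrsf4 (−1.24 ± 0.17). The naive gene Igfbp4 was at −1.47 ± 0.13. Checkpoints had 3 of 20 negative (adjusted p = 4.19e-08, 0.377 estimated) and tissue and effector Treg genes 2 of 25 (adjusted p = 1.22e-07, 0.377 estimated), or 8 and 8 over the lists alone. Naive and lymphoid homing passed with 1 of 20 negative (4 over the list alone, with 1 positive; adjusted p = 6.56e-05, 0.728 estimated), and proliferation with 0 members called (adjusted p = 0.00292, 0.911 estimated). Proliferation lost its call without TB spleen Treg library 2 (0.226) or TB spleen Tconv library 1 (0.0508). Some lists passed only with 1 library left out. Without TB spleen Treg library 1 these were chemokine receptors (0.00212), interferon response (0.00361), immediate early genes (0.00641), macrophage markers (0.00658) and ribosomal proteins (0.0246), and without library 2 interferon response in the other direction (0.0331). Without TB spleen Tconv library 2 they were chemokine receptors (2.02e-04), immediate early genes (2.58e-04), interferon response (0.0149), cytotoxic genes (0.0305), IL-33 and ST2 signalling (0.0340), glycolysis (0.0340) and macrophage markers (0.0438). Chemokine receptors also passed without normal spleen Treg library 2 (0.00626). The count of 115 is sensitive to single libraries: 56 or 45 without TB spleen Treg library 1 or 2, 63 or 56 without normal spleen Treg library 1 or 2, 55 without TB spleen Tconv library 2, 59 or 42 without normal spleen Tconv library 1 or 2, and 216 or 221 without tumour Tconv library 1 or 2.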

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

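The tests of leftover Treg, of RNA from tumour or stromal cells, of mast cells and basophils, of dissociation and of receptor signalling were chosen only after the results were seen.

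Treg and Tconv differed in how they changed between tumour and TB spleen at 3337 genes, and between TB and normal spleen at 115 genes. The genes below are given because the test of this difference passed. Values are the log2 change in Treg minus that in Tconv ± SE. Without 1 library the first number ran from 2161 (without TB spleen Treg library 1) to 3679 (without tumour Treg library 2). The second was 56 or 45 without TB spleen Treg library 1 or 2, 63 or 56 without normal spleen Treg library 1 or 2, and 55 without TB spleen Tconv library 2. It was 59 or 42 without normal spleen Tconv library 1 or 2, and 216 or 221 without tumour Tconv library 1 or 2.

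Between tumour and TB spleen, the largest positive differences among well-counted genes (mean log2 CPM of at least 3) were in Plac8 (5.96 ± 0.39), Cxcr6 (5.23 ± 0.23), Id2 (3.94 ± 0.17), App (3.42 ± 0.35), Serpina3f (3.41 ± 0.32) and Ccr2 (3.30 ± 0.37). A positive difference means a higher log2 change in Treg, and not a higher level in Treg. Differences between 2 and 3 were in Ccl5 (2.88 ± 0.27), Il2ra (2.63 ± 0.21), Tbx21 (2.41 ± 0.28), Socs2 (2.35 ± 0.26) and Nkg7 (2.26 ± 0.27). Smaller positive ones were in Ndrg1 (1.68 ± 0.09), Igfbp4 (1.61 ± 0.13), Oasl1 (1.34 ± 0.23), Usp18 (0.91 ± 0.15), Myd88 (0.51 ± 0.09), Irak2 (0.48 ± 0.12), Ccr7 (0.48 ± 0.11) and Nfkbia (0.36 ± 0.10). The largest negative differences among these genes were in Gucy1a3 (−3.57 ± 0.25), Atp6v0d2 (−3.07 ± 0.54), Sh3bgrl2 (−3.02 ± 0.28), Plxnb2 (−2.94 ± 0.49), Tnfsf11 (−2.88 ± 0.13) and Trim13 (−2.70 ± 0.22). They were followed by Tcf7 (−2.46 ± 0.19), Il1rl1 (−2.39 ± 0.50), Nsg2 (−1.99 ± 0.17), Gpr83 (−1.83 ± 0.17) and Irf4 (−1.71 ± 0.13). Smaller negative ones were in Nr4a3 (−1.32 ± 0.19), Nr4a2 (−1.24 ± 0.25), Slc16a5 (−1.22 ± 0.27), Tnfsf14 (−1.10 ± 0.36), Batf (−1.06 ± 0.12), Ccr8 (−1.03 ± 0.20) and Il1rap (−0.38 ± 0.12). Adjusted p ran from 1.26e-07 (Cxcr6, Id2 and Tnfsf11) to 0.0418 (Tnfsf14). Il1rl1 was at −3.21 without TB spleen Tconv library 1, Atp6v0d2 at −3.66 and −2.02 without tumour Tconv library 1 or 2, and Plxnb2 at −2.28 without tumour Tconv library 2. RNA of stromal cells was not excluded as a source of Il1rl1 in tumour Tconv. Tumour Tconv library 2 held more macrophage and fibroblast markers than library 1, and RNA of other cells was not tested as a source of Atp6v0d2 or Plxnb2.

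Between TB and normal spleen, the difference was positive in Cx3cr1 (3.86 ± 0.33), Epas1 (2.50 ± 0.21), Fam46a (2.01 ± 0.20), Fosl2 (1.97 ± 0.25), Rgs2 (1.55 ± 0.15), Rnf157 (1.51 ± 0.24) and Crem (1.24 ± 0.13). Among well-counted genes it was most negative in Neb (−4.46 ± 0.31), Coro2a (−3.44 ± 0.19), Socs2 (−2.76 ± 0.30), Il2ra (−2.17 ± 0.21) and Penk (−2.04 ± 0.20). Further negative ones were in Gucy1a3 (−1.99 ± 0.21), Ston1 (−1.67 ± 0.25), Igfbp4 (−1.47 ± 0.13), Tnfrsf4 (−1.24 ± 0.17), Nt5e (−0.99 ± 0.12) and Ctla4 (−0.97 ± 0.17). Adjusted p ran from 2.51e-06 (Coro2a) to 0.0178 (Ctla4).

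Of these 55 differences, 47 passed in each of 25 alternatives that kept the null of no change and the threshold of 0.05, and against a 1.5-fold change 40 passed. The other 8 were, with the range of adjusted p over the alternatives, Il1rap (0.0166 to 0.123), Tnfsf14 (0.00317 to 0.235), Nfkbia (0.00196 to 0.0820), Nr4a2 (6.71e-05 to 0.0657), Slc16a5 (0.00406 to 0.0501), Ctla4 (1.21e-06 to 0.192), Rnf157 (1.08e-07 to 0.0885) and Ston1 (2.48e-09 to 0.0956). With 1 library left out, Il1rap was lost in 9 of 12 cases (0.0567 to 0.123), and passed without tumour Treg library 2, tumour Tconv library 1 or normal spleen Tconv library 2. Tnfsf14 was also lost in 9 of 12 (0.0530 to 0.129), and passed without TB spleen Treg library 2, tumour Tconv library 2 or TB spleen Tconv library 2. Nfkbia was lost without TB spleen Treg library 2 (0.0717), tumour Tconv library 2 (0.0598) or TB spleen Tconv library 1 (0.0520), and Slc16a5 without tumour Treg library 2 (0.0501). Ctla4 was lost without TB spleen Treg library 1 (0.0778) or 2 (0.0954), normal spleen Treg library 2 (0.0727), TB spleen Tconv library 1 (0.0597) or 2 (0.0967) or normal spleen Tconv library 2 (0.127). Rnf157 was lost without TB spleen Treg library 2 (0.0567) or normal spleen Tconv library 2 (0.0812), and Ston1 without normal spleen Tconv library 2 (0.0691).

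Treg-associated genes were higher in spleen Tconv of TB mice than of normal mice, 12 of 20 of them. Leftover GFP-positive Treg in the sorted Tconv would bring Foxp3 along, yet Foxp3 was at −0.32 ± 0.14 with an upper bound (2 SE) of −0.0401. Scaling is not the source, since the median of the 20 genes was 1.15 with library-size scaling and 1.08 with TMM. A response to IL-2 through STAT5 is a candidate explanation: of 39 target genes 16 were higher and 1 lower in Tconv (camera p = 1.38e-06 and 0.00979 with preset and estimated correlation), such as Socs1 (1.55 ± 0.12) and Tnfrsf8 (2.51 ± 0.45), while in Treg 7 were higher and 4 lower (camera p = 0.0671 and 0.194). The gene called lower was Ltb (−0.39 ± 0.08), and Osm, Bcl2l1 and Myc were among those not called. The set was read from the same libraries and may change together with the Treg-associated genes, so the test is not independent of them. Tissue and effector Treg genes rose and naive genes fell in the same Tconv libraries, so the test cannot single out STAT5. The difference between the cell types in this set was not tested. Other signals that induce these genes, and former Treg that had lost GFP and Foxp3, were not tested.

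Il1rl1 was higher in tumour libraries of both cell types. In tumour Tconv libraries 1 and 2, leftover Treg at shares of 1.35% and 0.956% would explain 10.1% and 4.37% of Il1rl1. The shares were read from Foxp3, which gave larger ones than Klrg1. They assume that leftover Treg carried Foxp3 and Il1rl1 at the mean levels of sorted tumour Treg. Former Treg that had lost GFP and Foxp3 were not tested. Mast cells and basophils, which the CD4 enrichment and the sort should also remove, left Cpa3, Mcpt8, Ms4a2 and Fcer1a at a summed 0 to 0.451 CPM, at most 0.00750 of Il1rl1 in any tumour library. RNA of stromal cells would make Il1rl1 follow the fibroblast markers, but the ratio of tumour Treg to tumour Tconv was 5.43 times higher for Il1rl1 than for these markers, which argues against this source in Treg. In Tconv it cannot be told apart from expression by the sorted cells themselves, because at the ratio of Il1rl1 to markers in library 2 the markers could explain 61.6% of Il1rl1 in library 1, and a response of T cells to the tumour site stays open and untested.

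Immediate early and stress genes were higher in tumour than in TB spleen in both cell types. Tissue dissociation may raise them, and heat shock members rose too, by a median of 1.87 in Treg and 2.69 in Tconv. The strong rises were in the near-identical copies Hspa1a (4.42 ± 0.59 and 6.23 ± 0.52) and Hspa1b (3.08 ± 0.41 and 4.74 ± 0.39), on which the medians depend. Dnajb1 rose less (0.66 ± 0.10 and 0.64 ± 0.10), and Hsph1 was not called (−0.22 ± 0.17 and −0.20 ± 0.17). Antigen receptor signalling would raise receptor-induced genes, whose median was 2.06 in Treg and 3.07 in Tconv (Nr4a1 3.33 ± 0.13 and 3.63 ± 0.13). Egr2 and Egr3 nevertheless fell by 1.73 ± 0.20 and 1.35 ± 0.14 in Treg, and Egr3 fell by 0.54 ± 0.14 in Tconv. The 2 cannot be told apart, because any difference in how tumour and spleen were dissociated goes with the site, and most receptor-induced genes belong to the list itself.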

How the results depend on the processing

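The alternatives that kept only genes of a mean of 1 CPM in spleen or left out TB spleen libraries 1 of Treg and Tconv together were chosen after seeing the data. Where leaving out libraries left a group with 1 sample, that sample is assumed to vary like the other groups. The causes of the shifts below were not tested, except that fewer genes pass a stricter threshold by construction.

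With RLE size factors, library-size scaling, limma-voom, a robust fit, a mean of at least 5 CPM, a mean of 1 CPM in spleen or thinning to the smallest total, all 9 counts of genes stayed within 1.5 times the reported one. DESeq2 and no expression filter moved 1, the difference between cell types in how they changed with tumour bearing (115), to 211 and 184. Fits of only the groups compared gave 320 for it and 3670 instead of 2066 for tumour bearing in Treg. Other counts fell with these fits, though within 1.5 times. Tumour against TB spleen gave 4608 instead of 6639 in Tconv, with 1763 instead of 3077 lower, and 7918 instead of 8299 in Treg. With totals equalised by thinning, calls differed in 7 of 655 gene results. This tests unequal totals, and not whether more depth would add calls.

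Tested against a 1.5-fold change, tumour against TB spleen gave 3400 genes in Treg and 2545 in Tconv. Treg against Tconv gave 2693 in tumour, 1942 in TB spleen and 1864 in normal spleen, tumour bearing 113 in Treg and 191 in Tconv, and the interactions 568 (site) and 20 (tumour bearing). At an adjusted p below 0.01, tumour bearing gave 795 in Treg and 932 in Tconv, and the interactions 1731 and 43. Without TB spleen libraries 1, Treg against Tconv in TB spleen gave 3163, tumour bearing 728 and 779, and the interactions 1711 and 41.

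With each library left out in turn, tumour against TB spleen ran from 6846 to 8840 in Treg and 5258 to 6889 in Tconv, and Treg against Tconv from 6190 to 7251 in tumour, 4085 to 5964 in TB spleen and 3955 to 5975 in normal spleen. Tumour bearing in Treg ran from 512 (without normal spleen Treg library 2) to 2711 (without tumour Tconv library 2), with 856 and 683 without TB spleen Treg library 1 or 2 and 1010 without normal spleen Treg library 1. In Tconv it ran from 751 (without normal spleen Tconv library 2) to 2720 (without tumour Tconv library 2), with 1045 and 1450 without TB spleen Tconv library 1 or 2 and 985 without normal spleen Tconv library 1. The site interaction ran from 2161 (without TB spleen Treg library 1) to 3679 (without tumour Treg library 2), and the tumour-bearing interaction from 42 (without normal spleen Tconv library 2) to 221 (without tumour Tconv library 2). It was 56 or 45 without TB spleen Treg library 1 or 2, 63 or 56 without normal spleen Treg library 1 or 2, 55 without TB spleen Tconv library 2, 59 without normal spleen Tconv library 1 and 216 without tumour Tconv library 1.

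No gene result reversed a call under an alternative that gave a value for it. Some of the 655 had no value with a mean of at least 5 CPM, a mean of 1 CPM in spleen, DESeq2 or fits of only the groups compared. In 652 of the 655 with RLE, the side of the threshold was kept and no called value changed sign. The number was 649 with library-size scaling, 638 with limma-voom and 496 against a 1.5-fold change. The same held in 7542 of the leave-one-out results, with 268 calls lost and 50 gained. Values that were not called could change sign. Il33 in tumour Treg against Tconv went from 0.62 to −0.11 without tumour Tconv library 1. Of 225 list results, 71 lost the call with an estimated correlation and 154 stayed on their side. The leave-one-out fits kept 2614 list results, with 20 calls lost, 65 gained and 1 reversed. The interferon response list, not called in the tumour-bearing interaction (adjusted p = 0.786), ran from 0.00361 (without TB spleen Treg library 1) to 0.952 (without normal spleen Tconv library 1), and passed in the other direction at 0.0331 without TB spleen Treg library 2.

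A block on the replicate number of the titles, which assumes pairing the labels do not state, gave counts of 8273, 6581, 7269, 5430, 5446, 2077, 2300, 3327 and 141 in the order above. A block on the number in the sample description gave 818 and 1189 for tumour bearing in Treg and Tconv. Of the 655 gene results this block kept 621, with 27 calls lost and 7 gained. Deviations of equal replicate numbers correlated at −0.0639 to 0.264 between compared groups, and were positive between Treg and Tconv of the same site (0.0472 in tumour, 0.264 in TB spleen and 0.182 in normal spleen). In TB spleen the immediate early share was higher in library 1 of both cell types (0.413% against 0.278% in Treg, 0.424% against 0.236% in Tconv). Whether equal numbers share a mouse or a batch stays open.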

Other observations

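The sterol and glucocorticoid gene sets were written after the named genes had been seen and before the values of the genes tested here were looked at, and no test in this part was chosen after its own result.

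The sterol regulator Srebf2 was lower in spleen Treg and Tconv of TB mice. Synthesis genes had also been seen lower, Sqle and Fdps in Treg and Hmgcs1 and Cyp51 in Tconv. Lower sterol synthesis was therefore put forward as a hypothesis and tested on 13 synthesis genes that were in no fixed list. These were read from the same libraries and may change together with the genes already seen, so the test is not independent of them. In Treg 10 of the 13 were lower and 0 higher (median −0.41, camera p = 1.25e-08, or 0.0146 with an estimated correlation), including Mvk (−0.77 ± 0.16), Lss (−0.74 ± 0.13) and Mvd (−0.70 ± 0.12). In Tconv 6 were lower and 0 higher (median −0.35, camera p = 2.19e-04, or 0.0653 with an estimated correlation), including Fdft1 (−0.42 ± 0.09) and Ebp (−0.36 ± 0.06). With library-size scaling the medians were −0.34 and −0.27. Lower sterol synthesis in spleen T cells of TB mice remains a hypothesis, since only transcripts were measured and the labels give no measure of cholesterol.

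Genes induced by glucocorticoids could be raised by stress in mice with tumours, and this was tested on 7 such genes. Of these, 2 were called higher in Treg (median 1.16, camera p = 2.42e-06, or 0.00283 with an estimated correlation) and 3 in Tconv (median 0.53, camera p = 3.86e-04, or 0.0106 with an estimated correlation), and 0 were called lower. Fkbp5 rose by 1.16 ± 0.13 in Treg and 1.79 ± 0.14 in Tconv, Per1 by 1.07 ± 0.11 and 1.06 ± 0.11, and Zbtb16 by 1.30 ± 0.33 in Tconv. Tsc22d3 was not called (0.49 ± 0.23, adjusted p = 0.180, and 0.46 ± 0.23, adjusted p = 0.199). Nor were Mt1 (1.20 ± 0.65 in Treg and 0.53 ± 1.85 in Tconv), Mt2 (1.43 ± 1.41 and −2.58 ± 2.68) and Sgk1 (0.30 ± 0.18 and −0.31 ± 0.16). Zbtb16 was not called in Treg (3.04 ± 1.03). The Tconv median is thus the value of Mt1, with its large SE, and Mt2 and Sgk1 pointed down there. The result therefore rests on few genes. Per1 also follows the time of day, which the labels do not give, so a difference in sampling time stays open.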
